A study of Homo sapiens with 5 samples.

How the data were processed

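IRF4 chromatin immunoprecipitation followed by sequencing was compared between Karpas-1106p cells carrying IRF4-C99R (2 libraries) and Karpas-1106p cells with wild-type IRF4 (2 libraries, WT). An input library pooled from several samples is listed in the labels. It belongs to neither genotype, and no file of it was used here. Per the labels' protocols, chromatin was sheared by sonication and libraries were read as 75 nt single ends. The submitters' processing notes name BWA, MACS2 version 2.2.7.1, deepTools version 3.5.1 and the GRCh37 build, without giving their settings or the role of the input.

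The deposited files are 1 peak list per library, so peaks had been called in each library on its own. In each list the authors give, per peak, its interval and summit, a score, a fold enrichment over the local background at the summit, and the p and q of the peak as −log10 values. The deposited score equalled 10 times the deposited −log10 p, cut to a whole number, in at least 99.9998% of the peaks of each file. The deposited fold and −log10 p and q are the authors' values for single peaks and were used to describe, rank or filter peaks within 1 list. The lists hold peaks down to p of about 0.1, so most entries are weak. A peak was called strong at q up to 0.01 in its own library. Only chromosomes 1 to 22 and X were compared.

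The number of reads at each summit and the local background were recovered from the deposited fold and −log10 p. The fold was taken as (reads + 1) / (background + 1), and p as the Poisson chance of more reads than observed. The whole number of reads that met both was searched for every peak, with backgrounds from 0.5 reads upwards. It returned the deposited −log10 p within 0.001 for 100% of peaks in each library. The lowest local background of a library, its floor, served as its measure of depth. Ratios of reads between groups were divided by the floors, and their 95% intervals (exact, from the binomial split of the reads of 2 groups) cover counting error only. The relation was inferred from the values, not stated by the submitters. At summits that 2 libraries placed at the same base, with a background over 1.2 times the floor, the background was the same multiple of the floor within 1% in 100% of cases for each of the 6 pairs of libraries. Local background was therefore read from 1 control common to all lists and is not a separate measure of each library. A window with a local background over 5 times the floor in any library was called a high-background window.

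Windows of 201 bp were centred on the summits of strong peaks of all 4 libraries, in order of their rank within the library, and a window overlapping one already kept was dropped. A library counted as present where a strong peak of its own overlapped the window by at least 1 bp. A gained window was strong in both C99R libraries and in neither WT library, a lost window was the converse, and a shared window was strong in all 4. The other 2 of the 3 ways to split 4 libraries into 2 pairs gave the spread between replicates. With 2 libraries per group, an exact two-sided permutation test cannot go below p = 0.333, so no test across libraries was run on these counts. Nothing in the labels says whether the replicates were separate cultures or clones, so the spread may be technical. Shares carry exact (Clopper-Pearson) 95% intervals over windows, which are not replicates.

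The windows named were fixed by rule before the data were examined: the 12 gained and 12 lost windows with the highest lower value of their 2 within-library rank percentiles by −log10 p, and the 5 shared windows with the highest lowest percentile over 4 libraries. Windows are named by GRCh37 position. Planned searches for 17 motifs, for spacing of half-sites and for sequence words, the classes of genomic location, and 14 gene lists were not run, since no genome or annotation of that build was used here. The part of the rule that names genes of those lists was left out for the same reason.

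Differences in the gained share between the 23 chromosomes were tested by a permutation test of the chi-square statistic, and its relation to weak peaks (q over 0.05) by Pearson's r and Spearman's rho with 100000 permutations. For the stricter q, 1000 sets were simulated from the chromosome totals of that set and the gained shares at q up to 0.01, with the deviations in log odds multiplied by 0.679 to remove counting noise. Runs of at least 3 gained windows less than 50 kb apart were set against 1000 permutations of the classes among windows. Alternatives were stricter and laxer q, equal numbers of top peaks by −log10 p or fold, other overlap rules, absence of any listed peak, and leaving out each library. Added after the data were seen were a common p of 1e-05, the removal of high-background windows, q up to 1e-05 combined with no listed peak in the other group, and, for reads at shared windows, scaling each library to its mean log reads there. On simulated lists, reads were recovered for 99.995% of 20000 peaks, and all of 300 gained, 200 lost and 4000 shared windows were found with no false call among 500. No simulated weak peak came near the threshold, so this checks the code and not the rate of false calls in the real lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.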

Results

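IRF4, a transcription factor of the interferon regulatory factor family that acts in activated B cells and plasma cells, was profiled in Karpas-1106p, a cell line derived from primary mediastinal B-cell lymphoma. Cells carrying the IRF4 variant C99R were compared with cells with wild-type IRF4 (WT), with 2 libraries each. The question was whether the variant changes where IRF4 sits on chromatin. The lists held 1164122 and 1210041 peaks in the C99R libraries and 1356504 and 1332336 in the WT libraries. Depth, read from the lowest local background, was similar: the floor was 0.629 and 0.551 reads in C99R and 0.598 and 0.593 reads in WT. If each read was extended to 120 bp, the width of the narrowest listed peak, these floors equal 5.24, 4.59, 4.98 and 4.95 reads per kb.

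Strong peaks (q up to 0.01) numbered 15324 and 28398 in C99R libraries 1 and 2, and 23581 and 24165 in WT libraries 1 and 2. The group means were 21861 ± 9245 (SD, n = 2) for C99R and 23873 ± 413 (SD, n = 2) for WT, a difference smaller than the spread between the C99R libraries. The median fold enrichment of strong peaks was 4.91 and 4.57 in C99R and 4.45 and 4.56 in WT, and the highest was 52.3 and 63.4 against 55.5 and 64.5. Library 1 of C99R held 0.604 times as many strong peaks as the mean of the other 3, but 0.912 times as many at a common p of 1e-05. Its q limit fell at a −log10 p of 5.37, just above the 5.35 of a summit with 6 reads at the floor, so no strong peak of this library had 6 reads, against 10027, 8675 and 8299 in C99R 2, WT 1 and WT 2. At windows strong in all 4 libraries outside high-background windows, median fold enrichment was 7.51 and 8.81 in C99R and 7.69 and 8.35 in WT.

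The strongest IRF4 sites were shared most between libraries of the same genotype. Among the 5000 top peaks of each library, 65.7% overlapped between the C99R libraries and 64.7% between the WT libraries. Between genotypes the overlap was 58.5% ± 1.68 (SD, 4 pairs), and the highest of those pairs reached 60.4%. The exact two-sided permutation p over the 6 pairs was 0.133, the smallest these pairs can give, and the pairs are not independent. The gap was smaller relative to its spread with all strong peaks (32.6% ± 5.90 within and 29.1% ± 2.86 between genotypes, exact p = 0.4) and with 20000 top peaks (33.6% ± 2.05 and 30.4% ± 1.91, exact p = 0.267). In these wider sets the WT pair lay below the highest mixed pair (28.4% against 32.4%, and 32.1% against 32.8%). With 50000 top peaks it did so too (17.7% against 18.6%), so the order by genotype held only for the 5000 top peaks. After a shift of 1 Mb, at most 0.22% of the 5000 top peaks overlapped.

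**Figure D1:**
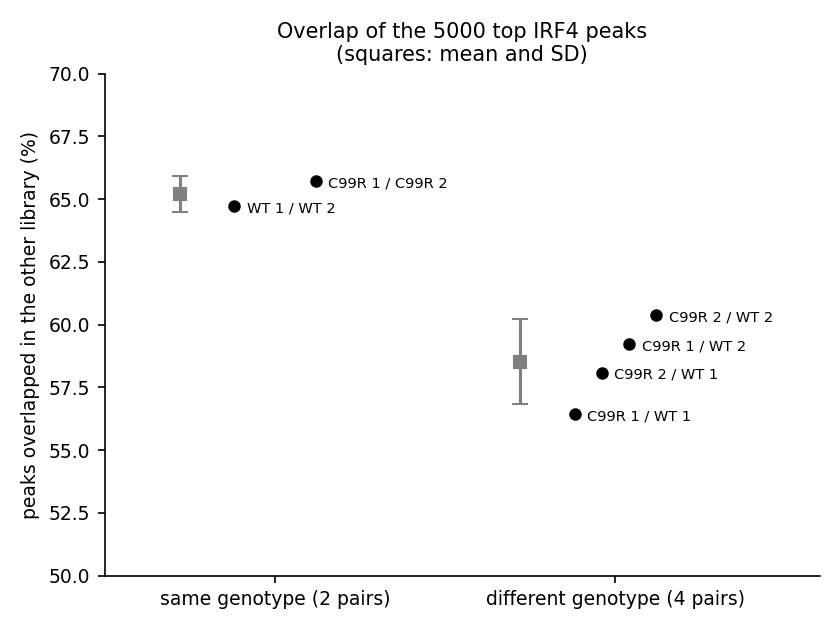
Share of the 5000 top IRF4 peaks of a library overlapped by those of another (%, vertical axis, from 50 to 70), for the 2 pairs of libraries of the same genotype and the 4 pairs of different genotype; squares with bars are means and SDs. Both pairs of the same genotype (64.7 and 65.7%) lie above all 4 mixed pairs (up to 60.4%).

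At gained windows, which lay on many chromosomes and were picked for strong peaks in C99R only, reads were higher in the C99R libraries. The variant cannot be told apart here from other differences between the cells of the 2 groups or in the preparation of their libraries. The leading gained window, on chromosome 5 from 55906291 to 55906491, held 26 and 28 reads at the summit in the C99R libraries and 3 and 5 in the WT libraries, a ratio of 6.81 (95% interval 3.22 to 16.6). A window on chromosome 5 from 171022819 to 171023019 held 25 and 21 reads against 3 and 4, a ratio of 6.63 (2.97 to 17.4). On chromosome 11, from 117309146 to 117309346, the C99R libraries held 28 and 20 reads and both WT libraries 5, a ratio of 4.85 (2.42 to 10.7). On chromosome 13, from 114520236 to 114520436, 34 and 29 reads stood against 6 and 8, a ratio of 4.54 (2.52 to 8.78). Windows on chromosome 1 from 39978008 to 39978208 (24 and 23 reads) and on chromosome X from 7572461 to 7572661 (27 and 24 reads) had no listed peak in either WT library.

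The 12 leading gained windows lay on 8 chromosomes and held 20 to 34 reads in C99R, with fold enrichments of 10.5 to 18.5. In 7 of them at least 1 WT library listed no peak, and where both did, the ratio ranged from 3.62 to 6.81. The other gained windows of this set start at 72177063 on chromosome 3, 11732511 on chromosome 6, 102707636 and 229034346 on chromosome 1, 100397232 on chromosome 14 and 52368114 on chromosome 13. The intervals cover counting error only, and the windows were picked for their difference, and a ratio so picked tends to overstate the difference. At q up to 0.05, where weaker WT peaks count as strong, 4 of the 12 were no longer gained, among them the windows on chromosomes 5 (from 55906291), 11 and 13 (from 114520236).

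At lost windows, picked for strong peaks in WT only, reads were higher in WT. That direction follows from the selection, and ratios so picked tend to overstate the difference. The leading lost window, on chromosome 11 from 18302087 to 18302287, held 19 reads in both WT libraries and 5 and 4 in the C99R libraries, 4.18 times as many in WT (1.99 to 9.84). On chromosome 18, from 53779728 to 53779928, WT held 17 and 24 reads and C99R 4 and 5, a ratio of 4.51 (2.16 to 10.6). On chromosome 8, from 136485489 to 136485689, WT held 13 and 16 reads and C99R 4 and 3, a ratio of 4.10 (1.76 to 11.1). The 12 leading lost windows lay on 9 chromosomes, held 13 to 34 reads in WT with fold enrichments of 8.31 to 15.7, and had ratios of 2.70 to 4.51 in the 11 where every library listed a peak. A window on chromosome 8 from 124549061 to 124549261 (34 and 26 reads in WT, 12 and 10 in C99R) was the one high-background window among them. At q up to 0.05 the window on chromosome 18 and 6 others of the 12 were no longer lost.

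**Figure D2:**
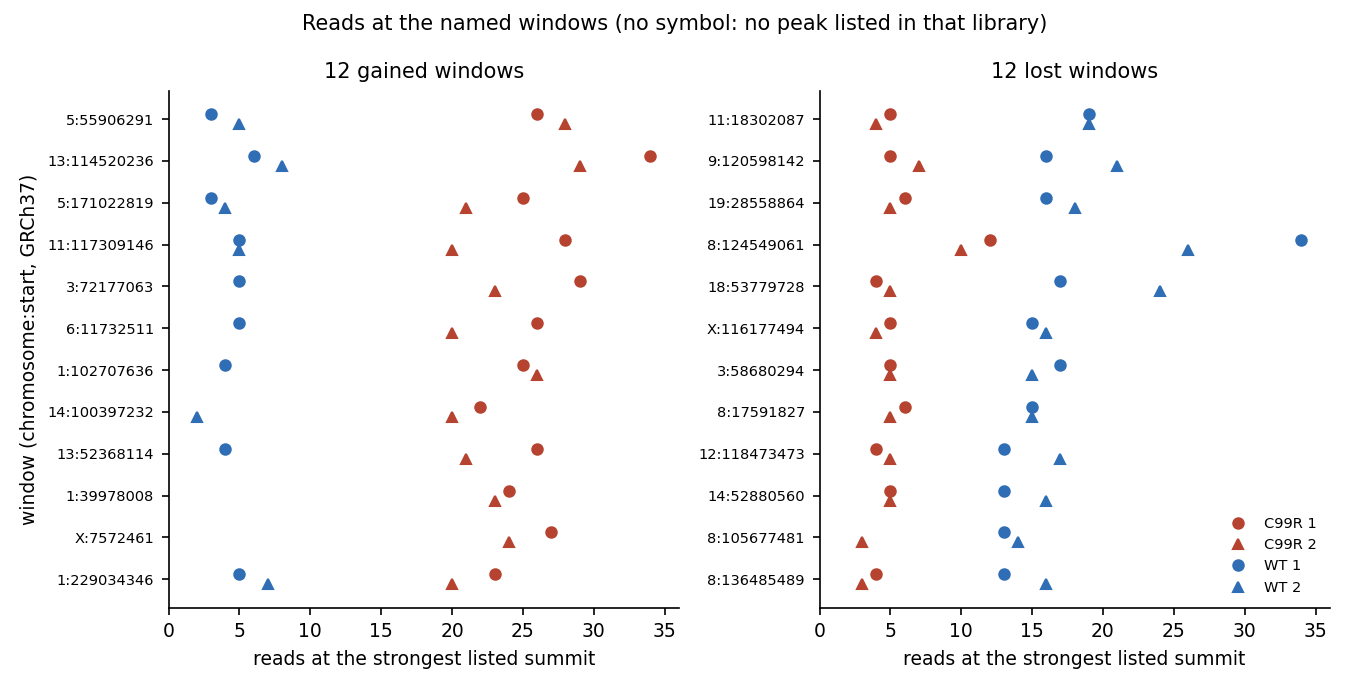
Reads at the strongest listed summit (horizontal axis) in each library at the 12 leading gained and the 12 leading lost windows, named by chromosome and GRCh37 start; red symbols are C99R libraries and blue symbols WT libraries, and a missing symbol means that no peak was listed. Gained windows held 20 to 34 reads in C99R and at most 8 in WT, and lost windows 13 to 34 reads in WT and at most 12 in C99R.

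The 5 leading shared windows, chosen for their rank in all 4 libraries and so unable to show a site of one genotype only, had similar reads in both. The window on chromosome 7 from 76786533 to 76786733 held 106 and 124 reads in C99R and 113 and 128 in WT, a ratio of 0.963 (0.801 to 1.16). On chromosome 9, from 98614935 to 98615135, the counts were 86 and 107 against 75 and 90, a ratio of 1.18 (0.954 to 1.46). The other 3 of the 5 leading shared windows, starting at 102354149 on chromosome 7, 111265970 on chromosome 6 and 95731929 on chromosome 14, had ratios between those values.

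Over the genome, 1598 windows were gained, 1122 were lost and 4438 were shared, out of 68389. Gained windows held a median of 10 reads in both C99R libraries, and 5 reads in each WT library where a peak was listed. In 58.8% of them both WT libraries listed a weaker peak, and in 10.8% (95% interval 9.29 to 12.4) neither did. Lost windows held medians of 8 and 9 reads in WT and 5 in both C99R libraries, and 9.18% (7.55 to 11.02) had no listed peak in C99R. Shared windows held medians of 17 and 18 reads in C99R and 16 and 18 in WT.

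The 2720 gained and lost windows exceeded what other pairings of the same libraries gave. Setting the libraries numbered 1 against those numbered 2 left 1483 windows strong in one pair only, and the remaining pairing left 1352. The lost count alone was close to the highest count of a single pair in these pairings, 1090 for C99R 2 with WT 2. At q up to 1e-05, 697 windows were gained and 473 lost, a total of 1170 against at most 549 for the other pairings, and among the 5000 top peaks 593 were gained and 483 lost, 1076 against at most 421. Gained windows made up 58.75% of the gained and lost ones (56.9 to 60.6), against 26.5% and 35.3% for the pair that holds C99R 1 in the other pairings, shares that move with the low number of strong peaks in that library. With 5000 top peaks from each library the share was 55.1%, against 46.7% and 51.3%, and with 20000 it was 59.6%, against 35.8% and 46.3%, so pairs of replicates also gave unequal counts. Most windows (81.0%) were strong in 1 library only, so each count rests on both libraries of a group: the gained count rose to 19892 without C99R 1, to 8354 without C99R 2 and to 2508 without WT 2, and the lost count to 16163 without WT 1, 16179 without WT 2 and 2116 without C99R 2. The gained share then fell below 50%, to 11.9% without WT 1 and 13.4% without WT 2, and it was 35.1% with the libraries numbered 1 alone.

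**Figure D3:**
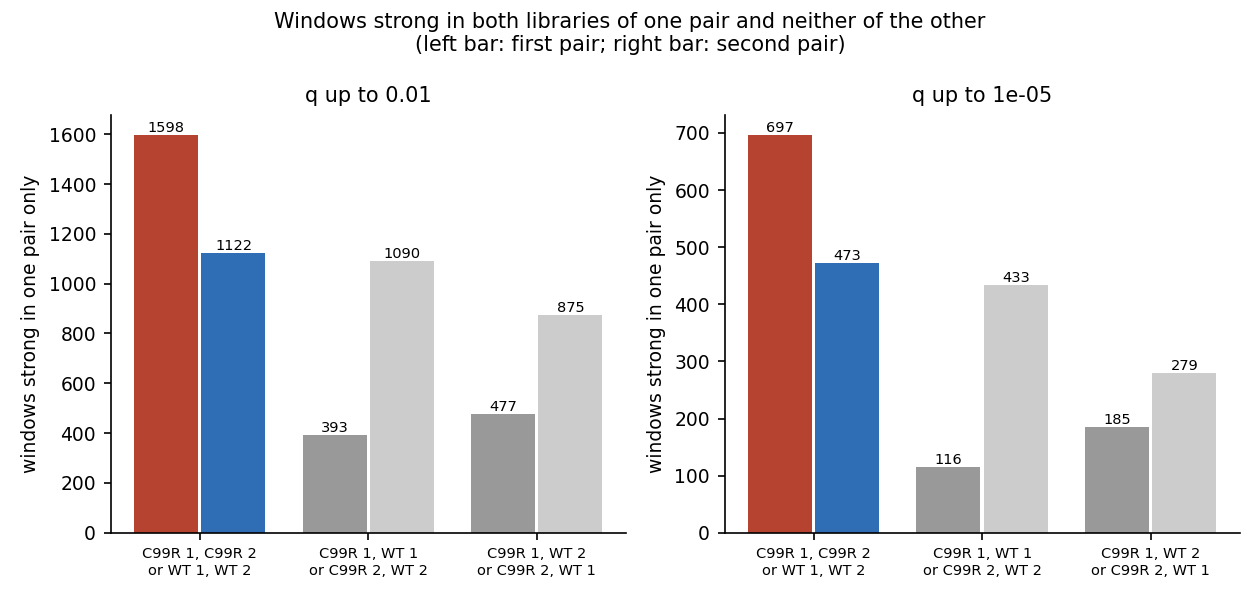
Number of windows strong in both libraries of one pair and neither of the other (vertical axis), for the 3 ways to pair the 4 libraries, at q up to 0.01 and q up to 1e-05; red bars are gained windows, blue bars lost windows, and grey bars the other pairings. The genotypes give 1598 and 1122 windows at q up to 0.01, and no other pairing gives more than 1090 for one of its pairs.

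Reads at shared windows were compared in the same way. Of 3843 shared windows outside high background, 833 had both C99R libraries above both WT libraries after scaling by the floor and 696 the reverse, together 39.8%. The pairing by replicate number set apart 35.4%, but nearly one way (202 against 1157, median log2 ratio -0.23), and the remaining pairing set apart 24.9% (359 against 596), with 33.3% by chance. Each window without ties is set apart by exactly 1 pairing, so these shares are not independent of each other. A difference of at least 2-fold with that separation was seen in 132 windows for C99R and 48 for WT, against 5 and 65, and 4 and 18, in the other pairings. With each library scaled to its own mean log reads at these windows, a setting chosen after the data were seen, 44.7% were set apart by genotype (812 against 907), and the SD of the log2 ratio over windows was 0.48 by genotype and 0.35 by each other pairing.

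Gained windows were more frequent relative to lost ones on some chromosomes. The gained share was highest on chromosomes 16 (69.4%, 58.5 to 79.0), 22 (68.3%), 19 (67.0%) and 17 (66.7%), and lowest on chromosomes 18 (43.8%, 31.4 to 56.7) and 4 (47.0%). The difference between the 23 chromosomes gave a chi-square of 40.8 and a permutation p of 0.00728 (Benjamini-Hochberg adjusted 0.0323 over 6 tests), and the same test gave p = 0.867 and 0.955 for the other pairings. Those pairings held fewer windows (1483 and 1352, against 2720), so the test had less power there. Classes were permuted among windows, which are not replicates, so p leaves out the spread between libraries. With the 1170 windows at q up to 1e-05 the permutation p was 0.579, but 1000 simulated sets of that size, with the differences seen at q up to 0.01 less counting noise, passed 0.05 in 32.7% of cases. Across chromosomes the share rose with the log2 ratio of weak peaks between C99R and WT (Pearson's r 0.667, permutation p = 0.00061, and Spearman's rho 0.704, permutation p = 0.00034). That log2 ratio ranged only from -0.024 to 0.055.

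**Figure D4:**
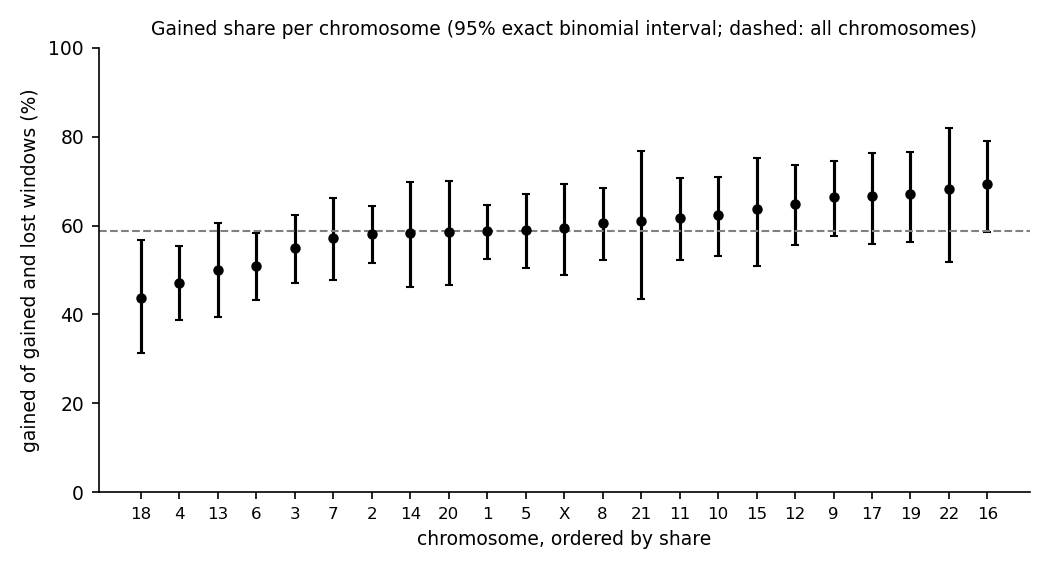
Gained windows as a share of gained and lost windows (%, vertical axis) on each of 23 chromosomes (horizontal axis, ordered by share), with exact 95% binomial intervals; the dashed line is the share over all chromosomes, 58.75%. Chromosomes 18 and 4 lie lowest and 22 and 16 highest.

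The run with the most gained windows, chosen after its values were seen, covered 46.4 kb of chromosome 8 from 129076578 to 129122976, with 6 gained windows among 14. At its strongest site, from 129115918 to 129116118 and strong in all 4 libraries, C99R held 73 and 85 reads and WT 32 and 42. At 129095588 to 129095788 C99R held 51 and 49 reads and WT 18 and 19. The window from 129076578 to 129076778 held 43 and 32 reads in C99R and 9 in WT 1, with no listed peak in WT 2. The 6 gained windows were higher in C99R by definition; of the other 8, both C99R libraries lay above both WT libraries in 5 and below them in 0. Of the 13 windows within 75 kb on either side, C99R was higher in 5 and WT in 1. The local background, which comes from 1 control common to the 4 lists, was 6.55 to 7.71 times the floor at the median of the peaks listed there, and away from the windows listed peaks covered 13.6% and 18.9% of the segment in C99R but 0.76% and 2.71% in WT.

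**Figure D5:**
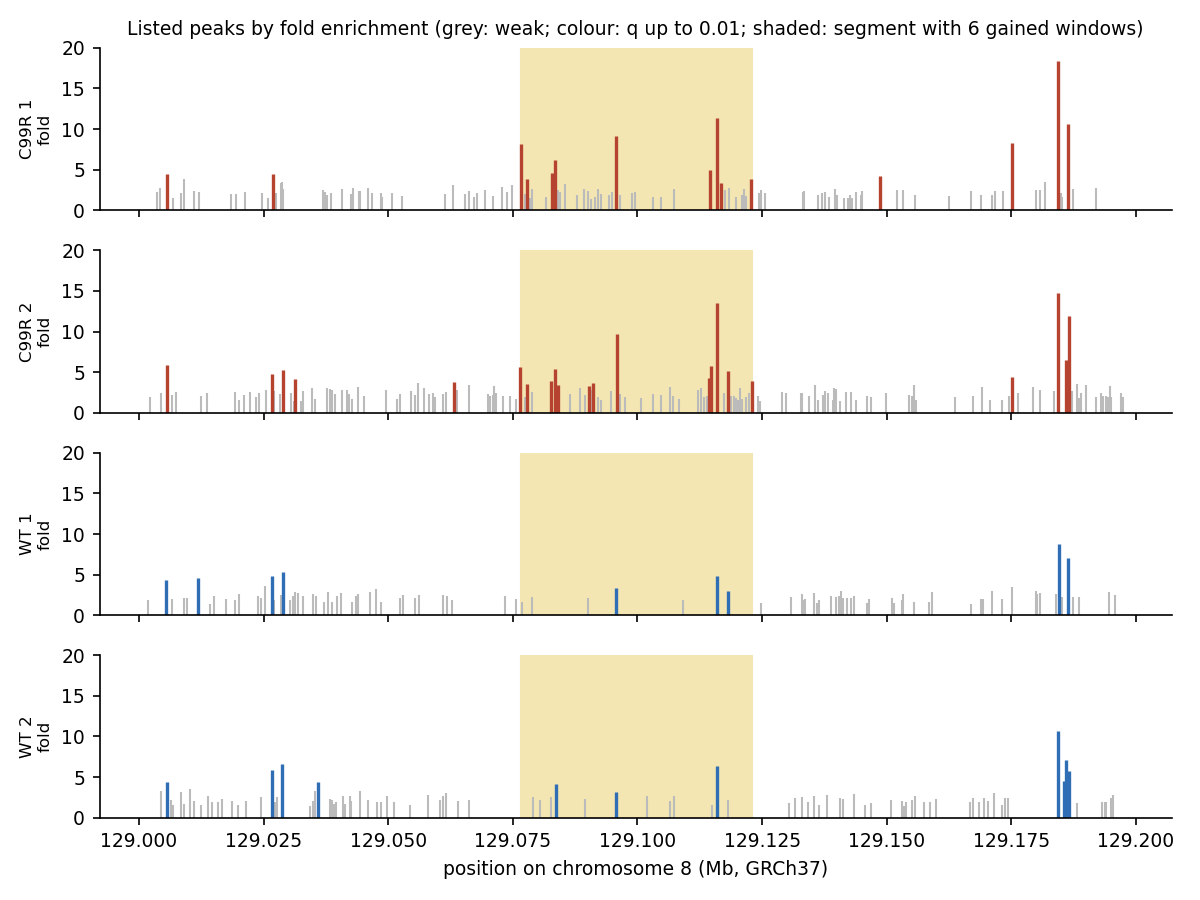
Listed peaks on chromosome 8 around the segment from 129076578 to 129122976 (GRCh37, position in Mb on the horizontal axis), each drawn as a line as high as its fold enrichment, in 1 panel per library; coloured lines have q up to 0.01, grey lines are weaker, and the shaded band is the segment. Within the band the C99R libraries have 9 and 13 strong peaks and the WT libraries 3 each, and weak peaks thin out in WT.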

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

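No tests were chosen after the results in this part were seen, and no explanation was tested. Contigs and sequences outside the numbered and sex chromosomes took no part in any comparison, and signal was present there in every library. Strong peaks on them numbered 260 and 333 in the C99R libraries and 284 and 294 in the WT libraries. A single unplaced contig held 161 and 180 of these in C99R and 166 and 177 in WT.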

How the results depend on the processing

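The gained count exceeded the lost count under all settings that kept 4 libraries, and the total exceeded that of both other pairings in each. At q up to 1e-05, 697 windows were gained, 473 lost and 2312 shared, and of the gained and lost ones 329 and 156 were among those of q up to 0.01. At q up to 0.05, 2965 were gained (64.6% of gained and lost), and the total of 4593 was 1.21 times that of the next pairing. With 5000 top peaks the counts were 593, 483 and 2161 shared, a gained share of 55.1%. With no listed peak in the other group they were 172 and 103 (62.5%), and also at q up to 1e-05, a setting chosen after seeing the data like the next, 38 and 11 (77.6%). A common p of 1e-05 gave a gained share of 62.7%. Leaving out 1 library gave 2191 to 19892 gained, 1535 to 16179 lost and 4827 to 5416 shared windows, and the gained share, 11.9% to 92.8%, reversed without WT 1 (11.9%) and without WT 2 (13.4%). By construction, 1 library left in a group contributes peaks that no replicate repeats. No paired analysis was possible because the result, a count of gained and lost windows, comes from no test and its rule is unchanged by pairing. This reason does not cover reads at shared windows, where a comparison within each replicate number could have been made but was not run. There, libraries numbered 1 and 2 were offset (202 against 1157 windows, median log2 ratio -0.23). Whether libraries of the same number were prepared together is not stated in the labels. Libraries numbered 1 alone gave 9703 gained and 17956 lost windows (35.1%, reversed), and those numbered 2 alone 21274, 17009 and 7354 shared (55.6%). Overlap within and between genotypes was 65.2% and 58.5% with 5000 top peaks, and 18.7% and 17.2% with 50000. Over the settings of threshold, ranking and overlap, 8 gained and 5 lost of the 12 named windows each kept their class at q up to 0.05, 12 and at least 10 otherwise, and 5 of 5 shared ones in each. Motif, spacing, sequence word, location and gene list alternatives were not run. At these depths strong windows start at 6 to 7 reads, so absence of a strong peak does not show absence of binding.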

Other observations

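The tests chosen only after the result was seen were those of windows at q up to 1e-05 with no listed peak in the other group, of other pairings, of the chromosome trend in weak peaks, of runs of gained windows, of simulated sets of windows, of shared windows with rescaled libraries, and of a high background in the chromosome 8 segment.

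The clearest differences in listed peaks were windows at q up to 1e-05 in both C99R libraries with no peak of any strength listed in WT. They were 38 in number, against 11 in the opposite direction. A site with too few reads to be listed has no peak, so these windows do not show absence of binding in the other group. None of the 38 and 1 of the 11 was a high-background window, on chromosome 17 from 22257015 to 22257215, with a background 96.9 times the floor and fold enrichments of 1.99 and 2.17. Beside the 2 already named, they included windows on chromosome 16 from 76030527 to 76030727 (19 and 26 reads in C99R), chromosome 19 from 30078612 to 30078812 (23 and 16 reads) and chromosome 3 from 187820939 to 187821139 (22 and 41 reads). In the opposite direction, windows on chromosome 3 from 46411126 to 46411326 and on chromosome 15 from 97153620 to 97153820 held 11 and 14, and 15 and 12, reads in WT. These windows were chosen after their values were seen.

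Gained windows sometimes lay in groups. Outside high background there were 18 runs of at least 3 gained windows less than 50 kb apart, against a mean of 11.05 (6 to 18) in 1000 permutations of the classes, with a one-sided permutation p of 0.0290 (0.0579 after Benjamini-Hochberg adjustment over 2 tests). Lost windows formed 2 runs, with a mean of 4.26 expected and a permutation p of 0.938. A run of 4 gained windows on chromosome 13 from 48730595 to 48758827 held 49 and 47 listed reads in C99R and 16 and 15 in WT, and another run of 4 spanned chromosome 12 from 53766447 to 53893331 (44 and 34 against 20 and 14). A pair of neighbouring runs of 3 on chromosome 5 spanned 150439339 to 150485964 and 150590619 to 150643885. Clustering beyond that of all windows is a hypothesis that the adjusted p leaves open.

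The excess of gained and lost windows over the other pairings was weighed against noise and copy number. Counting noise at the threshold as the whole cause is argued against by the 12.25-fold excess among windows at q up to 1e-05 with no listed peak in the other group (49 against at most 4, or 48 against at most 3 without high-background windows). This setting was chosen after the data were seen, rests on few of the 2720 windows and gave the largest excess of all settings. The other settings gave 1.21-fold (q up to 0.05) to 2.56-fold (5000 top peaks). Copy-number differences over megabases are argued against by the 4.63% of gained windows in 5 Mb bins whose weak peaks were raised in C99R, close to the 3.92% of shared windows. Of the lost windows, 1.07% (12 windows) lay in bins lowered in C99R, against 0.361% of shared ones, so such bins could account for few of them. Differences over shorter distances are argued against by weak peaks 0.5 to 25 kb from gained windows, whose median log2 ratio was 0.0266 above that at shared windows. For lost windows the same comparison gave -0.0441. Yet weak peaks were over 2-fold higher in C99R around 13 of 1598 gained windows, against 15 of 4265 shared and 1 of 1122 lost windows. They were over 2-fold higher in WT around 0, 2 and 2 of these. The genotype, other differences between the cells of the groups, and a culture or preparation shared within a group stay open. Only 1 of the 3 pairings, the real one, gave as many windows (2720, against 1483 for the highest other), and 3 pairings cannot give a share under 0.05. The labels do not say whether replicates were separate cultures, so the other pairings may understate the spread between preparations.

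The uneven gained share across chromosomes followed a trend in weak peaks. Across the 23 chromosomes it rose with the log2 ratio of weak peaks between C99R and WT (Spearman's rho 0.704, permutation p = 0.00034, adjusted 0.00068 over 2 tests; Pearson's r 0.667, p = 0.00061), and without chromosomes 19 and 22 r was 0.609 (p = 0.00354). At q up to 1e-05 the rise was smaller but present (rho 0.491, permutation p = 0.0178; r 0.486, p = 0.0191), and without chromosomes 19 and 22 r was 0.337 (permutation p = 0.135). The log2 ratios between C99R and WT were small, from -0.024 (chromosome X) to 0.055 (chromosome 19). Between the C99R libraries they ranged more widely, from -0.086 (chromosome 9) to 0.039 (chromosome 5). A small chromosome-wide difference in weak peaks between the groups thus stays a candidate explanation. Whether it acts through windows near the threshold cannot be told apart from a loss of power: the permutation p of 0.579 at q up to 1e-05 rests on 1170 windows, and 11.5% of simulated sets, with the differences seen at q up to 0.01 less counting noise, gave a chi-square as low (2.3% without that correction).

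The segment of chromosome 8 from 129076578 to 129122976 may carry more copies in the C99R cells than in the WT cells. Listed peaks away from its windows covered 9.38 times as much of it in C99R as in WT. In 900 kb of upstream sequence they covered 10.9% and 11.3% in C99R and 11.9% and 10.7% in WT. Against upstream, the larger departure was the low cover in WT (0.76% and 2.71%), with 13.6% and 18.9% in C99R. Cover counts sequence past the listing limit against a common control, so 9.38 is not a ratio of copies. At its strongest site C99R held 73 and 85 reads and WT 32 and 42. A high background alone is argued against by the cover of the segment, since the background is 1 control for all lists. Yet the lower C99R library was covered 5.03 times as much as the higher WT library. The ratios of the other pairings, at most 0.199, follow from this order of the libraries and add no support. Broad weak binding of IRF4 along the segment stays open, and so does added binding on top of a copy difference. Of 13 windows within 75 kb on either side, 5 were higher in both C99R libraries and 1 in both WT libraries.

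Among shared windows, occupancy was set apart by genotype 1.13 times as often as by the highest other pairing, which is under the 1.2 set in advance for a difference beyond the replicates. That pairing holds a one-way offset between libraries numbered 1 and 2, and the shares of the 3 pairings sum to the whole, so a higher share by genotype lowers the others. With the offset removed, the SD of the log2 ratio over windows, which has no such sum, was 1.37 times that of the highest other pairing. A difference of shared sites between the groups beyond their replicates is thus a hypothesis, found and tested on the same 4 libraries, whose 3 pairings cannot exclude chance.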
